A study of Mus musculus with 12 samples.

How the data were processed

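Sorted haematopoietic stem and progenitor cells of mice aged 8 to 12 weeks were profiled by total RNA sequencing in 12 libraries, 3 for each of wild-type, Cd19-cre, Cdh5-creERT2 and Tie2-cre mice, the last 3 with floxed Gad1 and Gad2. Per the labels, cells were sorted into TRIzol LS, RNA was precipitated with linear polyacrylamide, and libraries were made with a stranded Takara SMARTer Pico kit. The surface markers of the sort were not given in the sources used here. The authors aligned reads with STAR 2.7.11b to GRCm39 and estimated gene levels with RSEM 1.3.1. The deposited values are TPM per gene and library, with each column adding up to the same total within rounding and no further scaling between libraries seen. Reads per library were not in the file, so depth was unknown and no counting error was computed. All 12 columns were used. A library column named WT-2 and a sample title WT-2 stand for different libraries by the labels, and libraries are named here by their columns (WT-1, WT-1b, WT-2).

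Of the gene identifiers, 51948 matched a symbol and a biotype in the reference annotation GENCODE M21, which is on GRCm38, and the rest are called unnamed. Genes with at least 1 TPM in at least 3 libraries were tested, 14476 in all and 11594 of them protein-coding. In R 4.3.3, limma 3.58.1 was fitted to log2(TPM + 1) of all 12 libraries with a term per group (eBayes with a trend). Contrasts were each deletion against WT, each pair of deletions, and an F test over the 4 groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A pseudocount of 1 understates changes of genes with low levels. Group values are means ± SD over 3 libraries, and log2 changes carry the standard error of limma. The report gives no fold change where a group was listed at 0. Fitted differences of such genes given elsewhere are set by the pseudocount and are neither folds nor bounds.

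Before the data were examined, 35 gene lists were fixed, of which 34 had at least 5 measured members. They were tested in each comparison with camera (preset correlation 0.01), adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way without comparing them with other genes. Members were counted by the p over all genes and by the p adjusted over the list alone. A list's median is given relative to the median of all genes tested. The rule for named genes, fixed at the same time, took for each deletion against WT up to 10 genes per direction that passed the test, did not overlap between groups, averaged at least 5 TPM in the higher group and had an established symbol, filled up to 5 by unadjusted p with genes not past the threshold. Pairs of deletions took 5 per direction and the F test 10. Gad1 and Gad2, GABA receptor genes of at least 1 TPM on average and up to 4 members of each list described were added. Gad1 and Gad2 were compared by two-sided exact permutation tests.

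Alternatives chosen with the rest before were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 TPM, median-of-ratios scaling, protein-coding genes only, the 2 compared groups only, a block for the replicate number, averaging WT-1 and WT-1b, and leaving out each library in turn. Chosen after seeing the data were leaving out Cd19-1, median-of-ratios scaling without Cd19-1 (called rescaled in the text), and the same also without WT-2. Median-of-ratios factors rested on 13297 genes above 0 in 11 libraries, and on 5252 genes in 12. The tests were tried on simulated data with 200 planted changes. List scores are means of log2 levels over a list's members. Correlations within groups were taken over residuals from group means, with exact p-values over the 432 reassignments of libraries within their groups. Positions are those of GRCm38.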

Results

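Total RNA of sorted mouse haematopoietic stem and progenitor cells was sequenced in 12 libraries, 3 in each of 4 groups. The mice were 8 to 12 weeks old. One group was wild-type (WT). The other 3 carried floxed alleles of Gad1 and Gad2, which encode the glutamate decarboxylases that make the neurotransmitter GABA, with a Cre recombinase driven by Cd19 (B cells), by Cdh5 in a tamoxifen-inducible form (endothelial cells) or by Tie2 (endothelial and haematopoietic cells). The groups are called Cd19, Cdh5 and Tie2 here, after the Cre driver. The series title gives the question as how GABA from several bone marrow niche cell types acts on these progenitors. Values were TPM, each transcript's share of its library on a fixed total, and the number of reads behind them was unknown, so no counting interval was given. Of the gene identifiers, 14476 reached 1 TPM in at least 3 libraries and were tested.

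The make-up of the libraries differed between the groups. Protein-coding genes held 28.7% ± 8.65 of the TPM in WT (SD, n = 3), 43.2% ± 5.74 in Cd19, 56.4% ± 12.7 in Cdh5 and 53.8% ± 1.00 in Tie2. Small noncoding RNA and identifiers absent from the annotation used held 64.8% ± 9.23 in WT, 50.05% ± 5.31 in Cd19, 33.4% ± 14.4 in Cdh5 and 35.3% ± 1.05 in Tie2. TPM adds up to a fixed total, so such shifts move all other genes. The median log2 change of all tested genes against WT was -0.20 for Cd19 (0.32 without Cd19-1), 0.91 for Cdh5 and 0.93 for Tie2. Gene lists are therefore given relative to that median, and gene changes also after rescaling the libraries by median-of-ratios factors, which put the median at 0.00, 0.01 and 0.01. Library Cd19-1 stood apart, with 5055 genes at 1 TPM or more against 11160 to 14144 in the other 11, and Spearman correlations with them of 0.506 to 0.571. The rescaled values leave Cd19-1 out, a choice made after the data had been seen. Xist, the noncoding RNA of the inactive X chromosome, was above 46 TPM in Cd19-3, cdh5-2, Tie2-1, Tie2-3 and WT-1b and at most 0.03 TPM in the other 7 libraries, so the groups held animals of both sexes in unequal numbers.

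**Figure D1:**
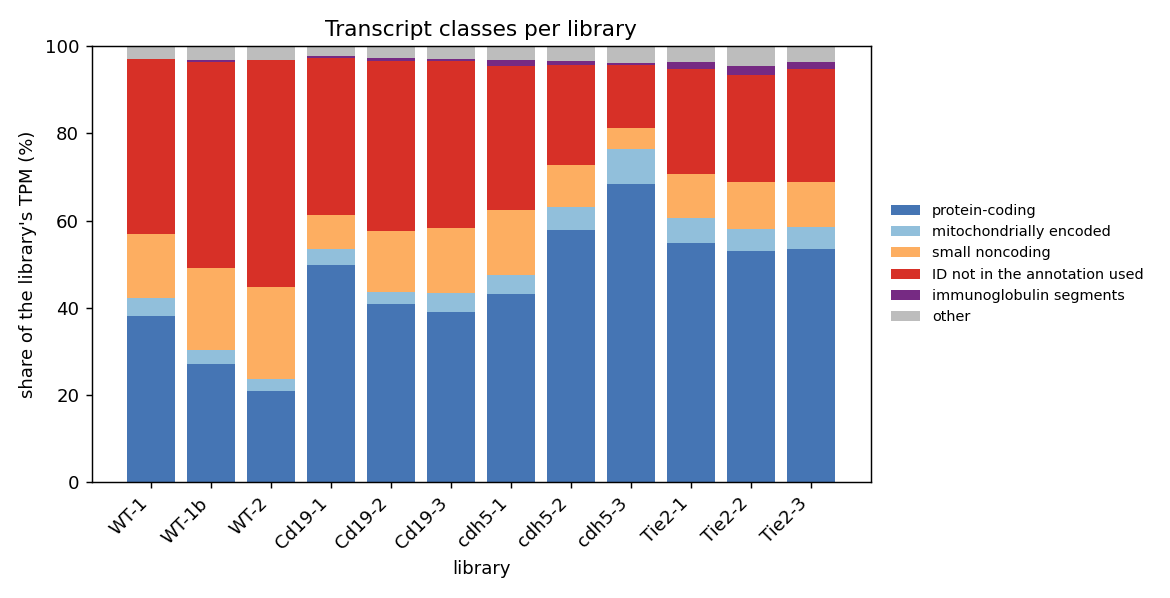
Share of each library's TPM (%) held by 6 classes of transcript, 1 stacked bar per library, in the order WT, Cd19, Cdh5, Tie2. The protein-coding share ran from 20.95% in WT-2 to 68.4% in cdh5-3, and identifiers absent from the annotation used ran from 52.0% to 14.6% in the same libraries.

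The targeted genes were near 0 in every group, WT included. Gad1 (chromosome 2, 70553072 to 70602014 on GRCm38) was listed at 0 TPM in 11 of 12 libraries and at 0.13 TPM in the other. Gad2 (chromosome 2, 22622205 to 22693874) was listed at 0 in 7 libraries and reached 0.15 TPM at most. The lowest p of a two-sided exact permutation test against WT was 0.4, where 3 against 3 libraries allow 0.1 at the lowest. A deletion could not be seen or ruled out from these levels. Of the 25 genes in the list of GABA receptors and their partners, 3 averaged at least 1 TPM. Gabbr1, a subunit of the metabotropic GABA-B receptor, averaged 1.65 ± 1.26 TPM in WT, 2.36 ± 2.22 in Cd19, 6.14 ± 3.21 in Cdh5 and 11.9 ± 2.59 in Tie2. The difference between Tie2 and WT was 2.39 ± 0.67 on the log2 scale (SE; limma adjusted p = 0.262) and 1.63 ± 0.34 after rescaling (adjusted p = 0.145), short of the threshold, with each Tie2 library above each WT library. Kctd12, an auxiliary subunit of the same receptor, was at 8.42 ± 4.66 TPM in WT and 24.1 ± 3.57 in Tie2, and the scaffold gene Gphn was at 2.59 ± 1.16 and 6.57 ± 0.42, and neither passed in any comparison. Against WT, the change of Gphn in Cdh5 was 0.71 and became -0.14 after rescaling. Gabbr2, the other GABA-B subunit gene in the list, reached 0.01 TPM at most. Whether the receptor was present was not tested.

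In the Tie2 libraries, 5 immunoglobulin genes rose against WT. Ighm, the constant region of the IgM heavy chain, averaged 2765 ± 344 TPM against 172 ± 199 in WT (log2 change 4.64 ± 0.75, adjusted p = 0.0481). Ighv1-18, a heavy-chain variable segment on chromosome 12, stood at 69.54, 56.88 and 58.76 TPM in the 3 Tie2 libraries and was listed at 0 in the other 9 libraries (adjusted p = 6.2e-06). Igkv3-12, a kappa light-chain variable segment on chromosome 6, stood at 12.39, 11.12 and 6.95 TPM in Tie2 and was listed at 0 in WT (adjusted p = 0.000718). Ighv1-5 rose by 6.69 ± 1.03 (adjusted p = 0.0408) and Igkv1-135 by 6.34 ± 1.00 (adjusted p = 0.0419). Socs2, a feedback inhibitor of cytokine signalling (chromosome 10), rose by 2.45 ± 0.40, from 0.07 ± 0.017 to 4.96 ± 1.48 TPM (adjusted p = 0.0493). Leaving out any 1 of the 6 libraries ended the calls of Socs2 (adjusted p = 0.134 to 0.317) and Igkv1-135 (0.0809 to 0.224). That of Ighm ended without any of them but WT-1b (0.143 to 0.318), and that of Ighv1-5 without any but Tie2-3 (0.104 to 0.318).

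Of the 14476 genes, 7 rose and 5 fell in Tie2 against WT by limma, and 2700 had an unadjusted p under 0.05. The seventh rise was that of Gm12013, a processed pseudogene listed at 0 in WT and at 20.70, 35.54 and 6.14 TPM in Tie2. The 5 that fell were the small nucleolar RNA gene Gm25419 and 4 identifiers that the annotation used does not name, all listed at 0 in the 3 Tie2 libraries. After rescaling, 10 genes passed, 3 higher and 7 lower, and 5 of the 12 were among them, Ighv1-18 and Igkv3-12 included. The adjusted p then became 0.161 for Ighm, 0.0548 for Socs2, 0.0587 for Igkv1-135 and 0.0821 for Ighv1-5. Past the threshold only after rescaling were 5 genes, with a fall of F13a1, a clotting factor subunit made by the monocyte lineage (-2.87 ± 0.32), a fall of Cst7, the protease inhibitor cystatin F (-1.77 ± 0.24), falls of BC035044 (-1.63) and of an unnamed identifier listed at 0 in Tie2, and a rise of Emcn, a surface sialomucin of endothelial and stem cells (1.91 ± 0.26). These 5 genes were read off after the values had been seen. Among protein-coding genes alone, rescaled to a common total, no gene passed by limma and 316 had an unadjusted p under 0.05. Without Tie2-1, Tie2-2, WT-1 or WT-2 the count of 12 was 6, 5, 5 or 5. With the Tie2 and WT libraries fitted alone it was 3418, of which 3306 rose.

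By lists fixed before the data were examined, macrophage, stem cell and B cell transcripts were higher in Tie2 relative to all genes, and granulocyte-monocyte and histone transcripts lower. All 15 macrophage genes passed when adjusted over the list alone, none of them over all genes, with a median 3.31 log2 units above that of all genes (camera adjusted p = 5.7e-06, and adjusted p = 0.786 with an estimated correlation). Axl, a receptor for dying cells, was 4.29 ± 1.21 higher, the haemoglobin scavenger receptor Cd163 4.23 ± 1.40 and the complement component C1qa 4.91 ± 1.72. Of 26 stem cell identity genes, Socs2 rose over all genes and 7 rose when adjusted over the list alone, with a median 0.82 above that of all genes (adjusted p = 1.6e-06, and adjusted p = 0.556 with an estimated correlation). Among the 7 were Fgd5, a marker of stem cells (2.03 ± 0.48), Eya1 (2.21 ± 0.63) and Cdkn1c, the inhibitor of cyclin-dependent kinases p57 (2.41 ± 0.69). After rescaling, all 26 were higher in Tie2 and 10 rose when adjusted over the list alone. Of 17 B cell genes, Ighm rose over all genes and 9 rose when adjusted over the list alone (median 0.80 above all genes, adjusted p = 1.9e-05, and adjusted p = 0.415 with an estimated correlation), among them the coactivator Pou2af1 (2.64 ± 0.64) and the pre-B cell receptor gene Vpreb3 (2.21 ± 0.64). After rescaling, 14 macrophage genes and 6 B cell genes rose when adjusted over the list alone. In WT, 8 of the 17 B cell genes, 12 of the 15 macrophage genes and 21 of the 26 stem cell genes averaged at least 1 TPM. A gene under that mean in WT was tested only if at least 1 deletion library reached 1 TPM, which favours a rise.

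Of 20 granulocyte-monocyte progenitor genes, none passed in Tie2 against WT, over all genes or adjusted over the list alone, and their median lay -0.97 log2 units from that of all genes (adjusted p = 4.4e-08, and adjusted p = 0.571 with an estimated correlation). After rescaling, 17 of the 20 were lower and 13 fell when adjusted over the list alone, among them the granule enzymes Ctsg (-2.37 ± 0.40) and Mpo (-2.11 ± 0.42). Of 63 replication-dependent histone genes, none passed, and their median lay -1.79 from that of all genes (adjusted p = 3.7e-58, and adjusted p = 0.285 with an estimated correlation). After rescaling, 62 were lower and 59 fell when adjusted over the list alone, by a median of -1.999, with Hist1h1b at -2.43 ± 0.52 and Hist1h2bp at -3.20 ± 0.61. The eosinophil, basophil and mast cell list of 13 genes had no gene past the threshold and a median of -1.46 from all genes (adjusted p = 4.1e-07, and adjusted p = 0.556 with an estimated correlation), with Prg3, an eosinophil granule protein, at 0.57 ± 0.31 TPM against 7.35 ± 2.87.

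Antigen presentation genes had 6 of 20 past the threshold in Tie2 when adjusted over the list alone, all of them rises, with B2m at 1.89 ± 0.45 and Cd74 at 1.99 ± 0.57 (list adjusted p = 0.00308, and adjusted p = 0.786 with an estimated correlation). After rescaling 1 of the 20 rose. NF-kappaB and inflammation genes had 2 of 19, Icam1 (1.87 ± 0.55) and Traf1 (1.72 ± 0.51), with a list adjusted p of 0.00803 and adjusted p = 0.786 with an estimated correlation. Of 21 immediate early genes, Fos rose when adjusted over the list alone (3.35 ± 0.72; list adjusted p = 0.0066, and adjusted p = 0.786 with an estimated correlation). Of 12 mitochondrially encoded genes, mt-Atp6, mt-Co3 and mt-Co1 rose when adjusted over the list alone (list adjusted p = 0.0181, adjusted p = 0.786 with an estimated correlation, and adjusted p = 0.174 after rescaling). After rescaling, none of the genes of these last 3 lists passed by limma, even adjusted over the list alone, and 6, 4 and 2 had an unadjusted p under 0.05. The erythroid list was lower, by a median of -0.09 with no gene of 22 past the threshold (adjusted p = 0.0357, adjusted p = 0.786 with an estimated correlation, and adjusted p = 0.116 after rescaling). The 82 ribosomal protein genes had a median of -0.02 and a mean of 0.03 relative to all genes and tested as higher (adjusted p = 0.00107, and adjusted p = 0.786 with an estimated correlation), and after rescaling they tested as lower (median -0.23, adjusted p = 4.9e-06). The 5 sex-linked genes tested as lower (adjusted p = 0.000814, adjusted p = 0.334 with an estimated correlation, and adjusted p = 0.415 after rescaling), with Xist in 2 of 3 Tie2 and 1 of 3 WT libraries. With 1 library left out, the immediate early list no longer passed without Tie2-1 (adjusted p = 0.0884), the mitochondrial list without Tie2-2 or WT-1 (0.0574 and 0.124), and the erythroid list without Tie2-1, Tie2-3, WT-1b or WT-2 (0.0512 to 0.229).

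In the Cdh5 libraries, the stem cell identity list was higher relative to all genes than in WT, and histone genes lower. Of its 26 genes, 12 rose when adjusted over the list alone and none over all genes, with a median 0.70 above that of all genes (adjusted p = 9.9e-05, and adjusted p = 0.879 with an estimated correlation). Hlf, a transcription factor of stem cells, was at 102 ± 45.8 TPM against 16.6 ± 13.0 in WT (2.75 ± 0.78), Fgd5 was 1.93 ± 0.48 higher and Cdkn1c 2.36 ± 0.69. After rescaling, 23 of the 26 were higher and 9 rose when adjusted over the list alone. Of 63 histone genes, none passed, and their median lay -1.62 from that of all genes (adjusted p = 1.5e-37, and adjusted p = 0.808 with an estimated correlation). After rescaling, 62 were lower and 59 fell when adjusted over the list alone, by a median of -1.80, with Hist1h4a at -2.57 ± 0.57. The libraries overlapped, with a histone score, rescaled and relative to the WT mean, of -0.70 in cdh5-1 and -1.15 in WT-1.

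Macrophage genes in Cdh5 had a median 2.28 above that of all genes with none of 15 past the threshold (adjusted p = 0.0149, and adjusted p = 0.879 with an estimated correlation), and Axl stood at 198 ± 266 TPM against 9.36 ± 2.35. Of 19 NF-kappaB and inflammation genes, 6 rose when adjusted over the list alone (list adjusted p = 0.0321, and adjusted p = 0.879 with an estimated correlation), among them the adhesion molecule Icam1 (2.07 ± 0.55), Ier3 (2.34 ± 0.63) and the chemokine genes Ccl3 (1.99 ± 0.56) and Ccl4 (1.79 ± 0.57). After rescaling 3 of the 19 rose. The granulocyte-monocyte list was lower with a median of -0.71 and no gene of 20 past the threshold (adjusted p = 0.0299, and adjusted p = 0.879 with an estimated correlation), and after rescaling 3 genes fell and Csf3r rose (1.04 ± 0.25) when adjusted over the list alone. The eosinophil, basophil and mast cell list was lower (median -0.95, adjusted p = 0.00162, and adjusted p = 0.879 with an estimated correlation). The megakaryocyte list (median -0.34, adjusted p = 0.0338) and the erythroid list (median -0.27, adjusted p = 0.0321) were lower, each with adjusted p = 0.879 with an estimated correlation, and neither passed after rescaling (adjusted p = 0.0722 and 0.11). The stress response list (median 0.26, adjusted p = 0.0299) and the glycolysis list (median 0.23, adjusted p = 0.0303) were higher, with adjusted p = 0.879 with an estimated correlation for each, and after rescaling their adjusted p was 0.309 and 0.449. The ribosomal protein list was higher by a median of 0.10 (adjusted p = 2.2e-06, and adjusted p = 0.879 with an estimated correlation) and after rescaling stood at -0.12 (adjusted p = 0.0821). Of 7 endothelial genes, 3 rose when adjusted over the list alone, and the list did not pass (adjusted p = 0.291). After rescaling the endothelial list passed by camera (adjusted p = 0.0207, and 0.311 with an estimated correlation). In WT, 3 of these 7 genes averaged at least 1 TPM, so the filter favours a rise. With 1 library left out, the macrophage list no longer passed without cdh5-3 or WT-1 (adjusted p = 0.204 and 0.324) and the granulocyte-monocyte list without cdh5-1 or WT-1b (0.328 and 0.0515). The megakaryocyte list was lost without cdh5-1, cdh5-3, WT-1 or WT-1b (0.0924 to 0.111) and the erythroid list without cdh5-1, cdh5-3, WT-1b or WT-2 (0.0783 to 0.147). The inflammation list was lost without cdh5-1, cdh5-3 or WT-1b (0.0625 to 0.111), the stress response list without cdh5-1, cdh5-2 or WT-1 (0.062 to 0.0944) and the glycolysis list without cdh5-1 or WT-1b (0.0823 and 0.0515).

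Over all genes, 1 rose and 4 fell in Cdh5 against WT, and 2653 had an unadjusted p under 0.05. The rise was that of Gm6829, a processed pseudogene on the X chromosome, at 8.14 ± 2.98 TPM against 0.06 ± 0.10 (3.07 ± 0.37, adjusted p = 0.00617). The 4 that fell were the small nuclear RNA gene Gm26264 and 3 identifiers without a name, all listed at 0 in Cdh5. Named by rank and not past the threshold were Bdh2 (2.38 ± 0.43, adjusted p = 0.18), Pcp4l1 (2.96 ± 0.54, adjusted p = 0.18), the lymphotoxin gene Ltb (2.78 ± 0.57, adjusted p = 0.263), the kappa segments Igkv16-104 (5.17 ± 0.98) and Igkv19-93 (6.12 ± 1.22), and at the other end the small nucleolar RNAs Snord15a (-1.24 ± 0.49) and Snord22 (-1.15 ± 0.46). Snord8 (-6.37 ± 2.57) and the 5S ribosomal RNA genes n-R5s28 (-5.70 ± 1.65) and n-R5s173, listed at 0 in Cdh5, completed that end. After rescaling, 15 genes passed, 3 higher and 12 lower, with rises of Emcn (1.91 ± 0.26) and of the interferon-induced membrane protein gene Ifitm1 (1.81 ± 0.24). Leaving out Cd19-1 without rescaling raised the counts from 5 to 5102 for Cdh5 and from 12 to 5232 for Tie2 against WT, with 4967 and 5141 of them rises. Cd19-1 is in neither comparison and enters only the shared estimate of the spread. The log2 changes were therefore the same with and without it, and the median gene stayed at 0.91 and 0.93. The larger counts came from the changed estimate of the spread, and the counts of 5 and 12 carry the spread of Cd19-1.

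In the Cd19 libraries, transcripts of bone marrow stroma, macrophages and B cells were higher than in WT relative to all genes. In WT, 3 of 12 stroma genes, 12 of 15 macrophage genes and 8 of 17 B cell genes averaged at least 1 TPM. A gene under that mean in WT was tested only if at least 1 deletion library reached 1 TPM, which favours a rise. Of 12 stroma genes, 3 rose when adjusted over the list alone, with a median 1.26 above that of all genes (adjusted p = 7.1e-07, and adjusted p = 0.15 with an estimated correlation). These were the collagen genes Col1a1 (26.2 ± 25.1 TPM against 0.42 ± 0.40; 3.78 ± 0.67) and Col1a2 (4.43 ± 0.96) and the matrix protein gene Sparc (3.68 ± 0.80). Of 17 B cell genes, Cd79b (2.21 ± 0.58), a chain of the B cell receptor, Igkc (3.28 ± 0.87) and Ighm (2.60 ± 0.75) rose when adjusted over the list alone (median 0.98, adjusted p = 0.000203, and adjusted p = 0.797 with an estimated correlation). The macrophage list was higher by a median of 2.03 with no gene past the threshold (adjusted p = 4.9e-05, and adjusted p = 0.884 with an estimated correlation), and after rescaling all 15 genes were higher and 12 rose when adjusted over the list alone. Its score, rescaled and relative to the WT mean, was 5.14 in Cd19-3 and 1.12 in Cd19-2, and without Cd19-3 the list no longer passed (adjusted p = 0.314).

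Of 7 endothelial genes, Plvap (3.06 ± 0.87), which forms the diaphragms of fenestrated endothelium, rose in Cd19 when adjusted over the list alone (list adjusted p = 0.0248, and adjusted p = 0.797 with an estimated correlation). Of these 7 genes, 3 averaged at least 1 TPM in WT, so the filter favours a rise here too. Lower than all genes were the 63 histone genes (median -1.63, adjusted p = 7.3e-11), the granulocyte-monocyte list (median -0.50, adjusted p = 0.0249) and the eosinophil, basophil and mast cell list (median -0.85, adjusted p = 0.0249), each with adjusted p = 0.884 with an estimated correlation and no gene past the threshold. After rescaling, the histone median was -0.80 (camera adjusted p = 3.0e-06, and 0.754 with an estimated correlation), and none of the 63 genes had an unadjusted p under 0.05. The histone scores of Cd19-2 and Cd19-3 (-0.67 and -0.84, relative to the WT mean) lay within the WT range of -1.15 to 0.88. In the granulocyte-monocyte list and the eosinophil, basophil and mast cell list, the Cd19 libraries went opposite ways. Rescaled and relative to the WT mean, the granulocyte-monocyte score was -1.08 in Cd19-2 and 0.37 in Cd19-3, where WT reached 0.20, and the eosinophil, basophil and mast cell score was -1.60 and 0.65, where WT reached 0.41. The latter list did not pass after rescaling (adjusted p = 0.0926). Without Cd19-2, WT-1b or WT-2, neither passed (adjusted p = 0.0567 to 0.285 and 0.0568 to 0.506), nor did the endothelial list without Cd19-2 or Cd19-3 (0.0862 and 0.0797). The ribosomal protein list was higher by a median of 0.64 (adjusted p = 9.5e-09, and adjusted p = 0.884 with an estimated correlation), and by 0.24 after rescaling. Over all genes, none rose and 4 fell by limma, where 853 had an unadjusted p under 0.05. The 4 were Gm26264 and the same 3 unnamed identifiers that fell in Cdh5, at 0 in all Cd19 libraries and at means of 6.15, 28.2, 12.9 and 18.5 TPM in WT. Without Cd19-3 the count was 8, and it was 0 by limma among protein-coding genes alone, where 1117 had an unadjusted p under 0.05. Named by rank and not past the threshold were Cd82, a tetraspanin (149 ± 104 TPM against 23.2 ± 13.4; 2.59 ± 0.62), the kappa segment Igkv14-126 (3.58 ± 0.88), F13a1 (-2.49 ± 0.65), Zfp965 (-2.31 ± 0.66), the channel kinase gene Trpm7 (-1.65 ± 0.49), Tmem68 (-2.11 ± 0.69) and n-R5s88 (-3.42 ± 1.12), with adjusted p = 0.73 for each.

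**Figure D2:**
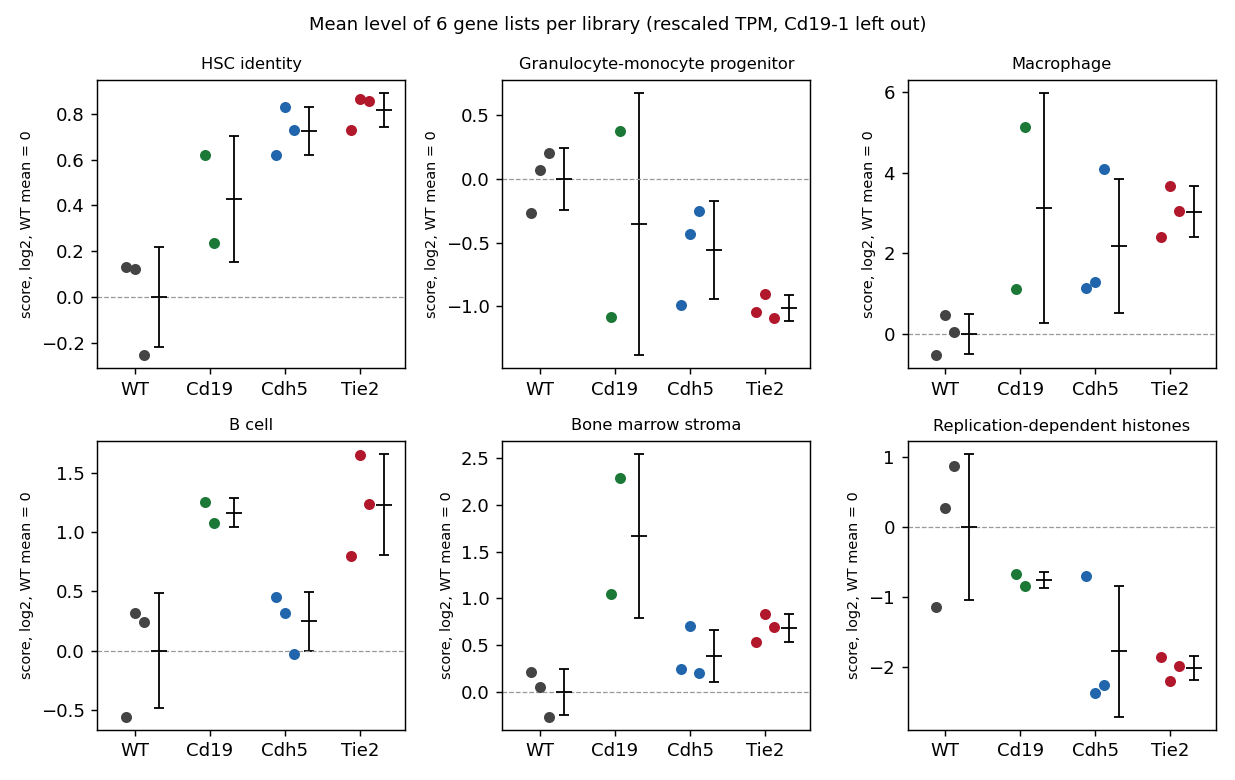
Mean log2 level of 6 gene lists per library, rescaled, with Cd19-1 left out and the WT mean set to 0. Points are libraries by group (n = 3, and 2 for Cd19), and bars give the mean ± SD. The macrophage score was at most 0.468 in WT and at least 1.12 in the 8 deletion libraries, and the stem cell score at most 0.13 in WT and at least 0.234 in the others.

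The 3 comparisons share the same 3 WT libraries, so genes moved by those libraries appear in each. Across genes, which are not independent replicates, the log2 changes correlated at 0.486 for Cd19 with Cdh5, 0.508 for Cd19 with Tie2 and 0.780 for Cdh5 with Tie2. Simulated groups without any difference gave 0.502, 0.502 and 0.505. The simulation gave all libraries 1 common spread per gene, Cd19-1 included, and no shift in make-up. Such values then follow from groups of equal size that share controls. The simulation cannot show that shared controls account for the first 2 correlations. The covariances were 0.396, 0.381 and 0.537, against 0.351 in the simulation for each. Of the unnamed transcripts that fell, 3 were shared by all 3 comparisons. They were listed at 0 in every deletion library, so their level in the shared WT libraries sets each of the 3 changes. The p-values throughout measure the spread between these libraries, since the labels do not say that each came from a different animal. For WT-1 and WT-1b, the sex genes argue against the same animal. Xist was at 0 TPM in WT-1 and 62.75 in WT-1b, and the Y-linked gene Ddx3y at 8.12 and 0 TPM. For libraries of the same sex within a group the question stays open. The fit also pools the spread of a gene over the groups. A group listed at 0 throughout adds no spread, so the standard error can be too small for a group that varies. An unnamed identifier shared by all 3 comparisons averaged 28.2 ± 25.3 TPM in WT, with a standard error of 0.49 in Tie2 against WT. This limit bears on every called gene listed at 0 in a whole group.

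The deletions were also compared with each other, where WT libraries enter only the estimate of the spread. Tie2 differed from Cdh5 in 2 genes and from Cd19 in 5, and Cdh5 differed from Cd19 in 2, all of them higher in the group named first, and 239, 3935 and 3944 genes had an unadjusted p under 0.05. Of the last 2 numbers, 3913 and 3892 were higher in the group named first, alongside a median change of all genes of 1.04 and 0.99. After rescaling the 3 numbers were 606, 1536 and 1161. With the 2 compared groups fitted alone, Tie2 differed from Cdh5 in 1 gene, and no gene passed by limma for Tie2 or Cdh5 against Cd19, where 1738 and 1036 had an unadjusted p under 0.05. Ighv1-18 and Igkv3-12 were higher in Tie2 than in both other deletions, by 3.22 ± 0.34 for Igkv3-12 against Cdh5 (adjusted p = 0.00301). Ighv1-5 was listed at 0 in Cd19 and averaged 237 ± 199 TPM in Tie2 (adjusted p = 0.0343, and 0.0637 to 0.135 without any 1 of the 3 Cd19 libraries, Tie2-1 or Tie2-2), and Gm12013 was also listed at 0 in Cd19 (adjusted p = 0.0379). mt-Atp6, a mitochondrially encoded subunit of ATP synthase, was 6.59 ± 0.86 higher in Tie2 and 6.66 ± 0.86 higher in Cdh5 than in Cd19 (adjusted p = 0.0203 and 0.027). It was listed at 0, 0 and 4.7 TPM in Cd19. All mitochondrially encoded genes together held 3.65% ± 0.83 of the TPM in Cd19, 3.37% ± 0.77 in WT, 5.83% ± 1.89 in Cdh5 and 5.32% ± 0.41 in Tie2. The low level of mt-Atp6 in Cd19 therefore does not stand for mitochondrial RNA as a whole, and its cause was not tested. After rescaling, with Cd19-1 left out, the adjusted p was 0.216 and 0.227 for mt-Atp6, 0.326 for Ighv1-5 and 0.33 for Gm12013. Gm6829 was 3.10 ± 0.37 higher in Cdh5 than in Cd19 (adjusted p = 0.0223). Between Tie2 and Cdh5 the count was 4 to 6 without cdh5-1, cdh5-2, Tie2-1 or Tie2-3, between Tie2 and Cd19 it was 2 without Tie2-2. Between Cdh5 and Cd19 it was 4 without Cd19-1 and 0 without Cd19-2 or cdh5-3. By the F test over the 4 groups, 10 genes changed and 2473 had an unadjusted p under 0.05, and Ighv1-18, Igkv3-12, mt-Atp6 and Ighv1-5 were those with established symbols. That count was 82 without Cd19-1 and 6 without Tie2-2 or WT-1.

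Of the gene lists, the 17 B cell genes were higher in Tie2 than in Cdh5 by a median of 1.21 (adjusted p = 1.1e-13, and adjusted p = 0.095 with an estimated correlation), and lower in Cdh5 than in Cd19 (median -0.81, adjusted p = 6.5e-06, and adjusted p = 0.435 with an estimated correlation). Stroma genes were lower in Cdh5 than in Cd19 by a median of -1.54 (adjusted p = 5.8e-11, and adjusted p = 0.0309 with an estimated correlation). Once libraries were rescaled and Cd19-1 was left out, the median was -1.26 (adjusted p = 4.9e-05, and adjusted p = 0.386 with an estimated correlation), and why the latter call ended was not tested. Col1a2 stood at 186.55 TPM in Cd19-1 and at 3.99 and 28.01 TPM in the other Cd19 libraries. Stroma genes were also lower in Tie2 than in Cd19 (median -0.80, adjusted p = 8.5e-07, and adjusted p = 0.144 with an estimated correlation). Col1a1 was at 0.43 ± 0.30 TPM in Tie2 and 0.80 ± 0.58 in Cdh5 against 26.2 ± 25.1 in Cd19, and none of its differences passed (adjusted p = 0.155 and 0.183). Named by rank and not past the threshold were Bdh2 and Ndrg2, higher in Cdh5 than in Tie2 (-1.53 ± 0.43 and -1.76 ± 0.61, adjusted p = 1), and the chemokine gene Ccl3, higher in Cdh5 than in Cd19 (2.81 ± 0.56, adjusted p = 0.183).

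**Figure D3:**
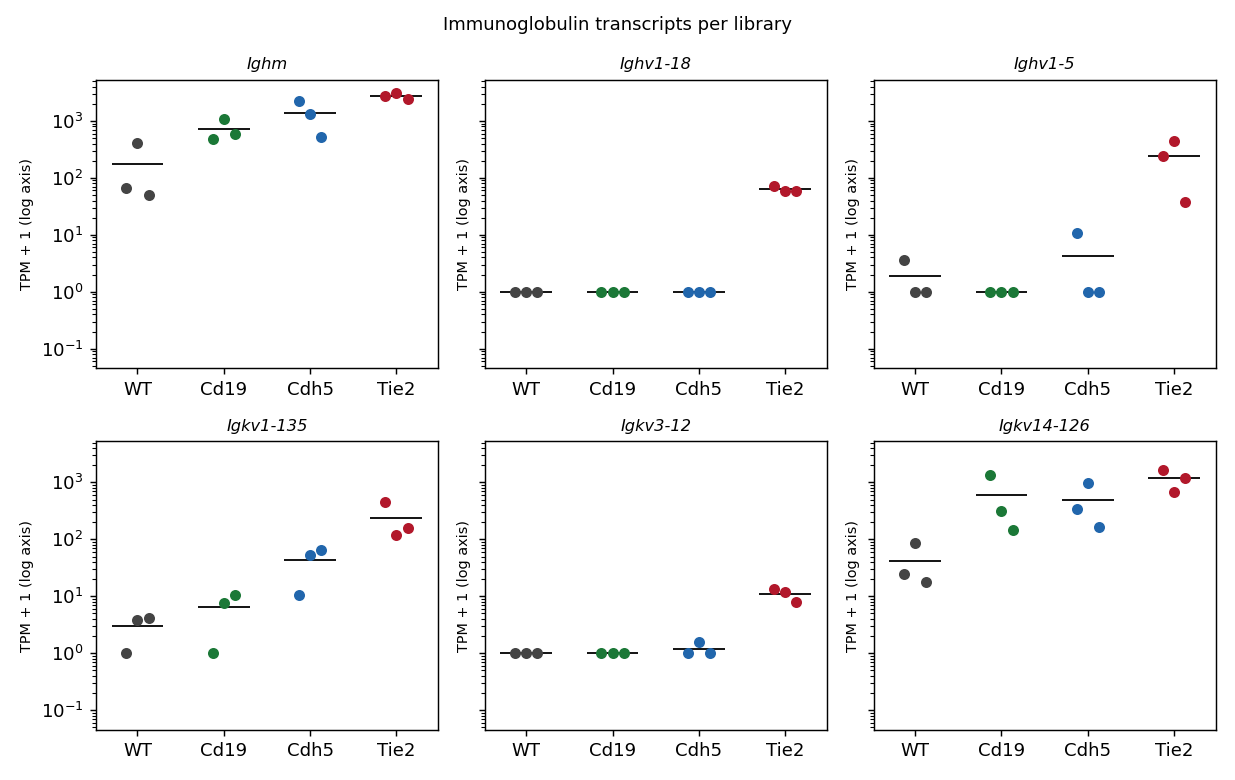
TPM + 1 of 6 immunoglobulin genes per library (log axis), with points for libraries, lines for group means and 3 libraries per group. Ighv1-18 stood above 56 TPM in each Tie2 library and at 0 in the other 9, and Ighm averaged 2765 TPM in Tie2 against 172 in WT.

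Of 34 lists tested, 18 were called in at least 1 of the 3 comparisons with WT, for 32 calls in all, and with an estimated correlation none of the 32 held, the lowest adjusted p being 0.15. The 16 lists called in none without rescaling (lowest adjusted p = 0.0629) were those for DNA replication, mitosis, quiescence, p53 targets, type I interferon, heat shock, ribosome biogenesis, cholesterol synthesis, nuclear-encoded respiratory chain, nuclear-retained RNA, adhesion, G protein signalling, GABA synthesis, lymphoid-primed progenitors, mature neutrophils and monocytes, and T, NK and plasma cells. After rescaling some of these passed by camera. Among them, in Cd19, ribosome biogenesis (adjusted p = 0.00107, and 0.543 with an estimated correlation) and nuclear-retained RNA (0.0219 and 0.534) tested as lower. Recovery was tried on values simulated with 1 common spread per gene for all libraries and no shift in make-up. Changes were planted in the simulated Tie2 group. With the spread of all 12 libraries, 0.4% of changes of 1 log2 unit and 41.8% of those of 3 units were recovered against WT. With that of the rescaled values, without Cd19-1, 17.2% and 84.8% were recovered. False calls averaged 1.8 per run, and 6.4 with the rescaled spread. These rates need not hold for the libraries themselves, whose spread and make-up differed.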

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

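The tests of S phase, of RNA without a poly(A) tail and of small RNA in the WT total were chosen only after the result they bear on was seen, as were the rescaled values, which leave out Cd19-1. The other tests here were set before.

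Differences between deletions were tested directly, and 6 genes and 1 gene list stood out in them. Against Cdh5, the Tie2 libraries were higher in Ighv1-18 (fitted difference 5.97, with all Cdh5 libraries listed at 0) and Igkv3-12 (3.22). Against Cd19, they were higher in Ighv1-18 (5.97), Igkv3-12 (3.44), Ighv1-5 (7.31) and Gm12013 (4.16), all 4 listed at 0 in Cd19, and in mt-Atp6 (6.59), listed at 0, 0 and 4.7 TPM in Cd19. Where a group is listed at 0, the fitted value on log2(TPM + 1) is set by the pseudocount and is neither a fold nor a bound. Cdh5 was higher than Cd19 in mt-Atp6 (6.66) and Gm6829 (3.10). Stroma genes were lower in Cdh5 than in Cd19 by a median of -1.54 relative to all genes (adjusted p = 0.0309 with an estimated correlation, and, rescaled without Cd19-1, a median of -1.26 with 0.386).

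Splits of the libraries were counted for each number of genes changed, the real split included. With 6 libraries there are 10 splits, too few for a share under 0.05. As many genes as in the real split were given by 2 splits for Cd19 against WT (real 4, highest other 4), 1 for Cdh5 against WT (5 and 2), 1 for Tie2 against WT (12 and 4), 5 for Tie2 against Cdh5 (2 and 7), 1 for Tie2 against Cd19 (5 and 4) and 4 for Cdh5 against Cd19 (2 and 7). For the 4 groups, 3 of 100 splits gave at least the real 10, the real split among them. That share is under 0.05 but was not adjusted for the other counts, so chance was not excluded. Another split gave 27, which points to a structure of the samples whose cause was not tested. The real count was 1 with a mean of at least 5 TPM, 0 by limma among protein-coding genes (513 unadjusted) and 82 without Cd19-1.

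Histone transcripts were lower in Cdh5 and Tie2, with rescaled medians of -1.80 and -1.999. Transcript length was argued against, since genes matched in length (median 542 against 539 bases) had medians no lower than -0.024, and fewer cells in S phase was argued against as the whole cause, since the DNA replication list had medians no lower than -0.213, though 27 of its 29 genes were lower in Cdh5 and 22 in Tie2, so a part stays open. Less RNA without a poly(A) tail in these libraries is a candidate explanation, as histone transcripts of dividing cells lack the tail and the small noncoding genes tested had medians of -2.27 in Cdh5 and -1.72 in Tie2. Within groups, the histone score was higher where the joint share of small noncoding RNA and identifiers absent from the annotation used was. This was over 11 libraries and short of the threshold once adjusted (r = 0.871, exact p = 0.0486, adjusted p = 0.0972 over 2 relations, rho = 0.773, exact p = 0.0972, and r = 0.923 without cdh5-1 and cdh5-3). The unannotated identifiers were the larger part (46.5% against 18.3% in WT) and of unknown kind, so the correlation does not speak for small RNA alone. Whether that share differed through the cells or the handling was not tested, and the deletion itself stays open as untested.

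Macrophage transcripts were higher in all 3 deletion groups, with Axl at 211 ± 85.0 TPM and C1qa at 150 ± 49.5 TPM in Tie2 against 9.36 ± 2.35 and 4.57 ± 3.78 TPM in WT. The larger part of small RNA in the WT total was argued against, since the lowest of the 3 rescaled medians was 2.17. RNA of macrophages in varying amount is a candidate source. Within groups the 15 genes moved together over 11 libraries, with a median pairwise correlation of 0.951. This was above all of 1000 lists of genes with matching levels (median -0.006). These were random genes, so any set of co-regulated genes could exceed them. The rescaled score was 1.12 in Cd19-2 and 5.14 in Cd19-3, and 1.15 in cdh5-1 and 4.09 in cdh5-3. It varied less within Tie2 and WT, so the correlation may rest largely on a few libraries, and it was not computed without them. Of the 15 genes, 12 averaged at least 1 TPM in WT and none is in another list, and a sort for stem and progenitor markers should remove macrophages, though its markers were not given in the sources used here. Whether macrophages were more frequent in these mice or more often caught with the sorted cells was not tested, and the deletion itself stays open as untested.

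Stem cell genes were higher and granulocyte-monocyte genes lower in Tie2, by a rescaled mean difference between the lists of 1.83. The larger part of small RNA in the WT total was argued against as the whole cause, since it acts by about one factor per library, which cannot open such a gap (1.65 before rescaling), and the gap was at least 1.77 in each Tie2 library and at most 0.40 in WT. A different mix of progenitors from library to library, which could arise in the sort or in the mice, cannot be told apart from a change within cells, since the within-group correlation of the scores was r = -0.533 (exact p = 0.435, adjusted p = 0.435 over 2 relations; rho = -0.518, exact p = 0.356) and r = -0.218 without WT-2 and Cd19-3. The rescaled mean difference between the 2 lists was also 1.28 in Cdh5 and 0.78 in Cd19, against the same WT libraries. It was thus not limited to Tie2, though the Cd19 libraries differed in granulocyte-monocyte score (-1.08 in Cd19-2 and 0.37 in Cd19-3). The deletion itself stays open as an untested explanation.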

How the results depend on the processing

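Leaving out Cd19-1 and both settings that rescale without it were chosen after seeing the data, and the other alternatives before. Where no reason is given, the cause was not tested. The numbers of genes changed moved with most settings. With a pseudocount of 0.1, Tie2 against WT gave 7 (12 in the report), Tie2 against Cdh5 1, Tie2 against Cd19 2 and Cdh5 against Cd19 0 (by limma, with 2608 at an unadjusted p under 0.05), and with a pseudocount of 5 Tie2 against WT gave 19. With no filter, Cd19 against WT gave 7, Tie2 against Cdh5 4, Cdh5 against Cd19 0 (4340 unadjusted) and the gene lists 61 calls. With a mean of at least 5 TPM the counts were 0 for Cd19 and 0 for Cdh5 against WT (650 and 1882 unadjusted), 1 for Tie2 against WT, 1 for Tie2 against Cdh5, 2 for Tie2 against Cd19, 0 for Cdh5 against Cd19 (2428 unadjusted) and 1 for the F test. Among protein-coding genes alone all 7 counts were 0 by limma, with 56 to 1347 genes at an unadjusted p under 0.05. That filter removes the immunoglobulin segments and unnamed identifiers. Median-of-ratios scaling gave 5 for Tie2 against WT (2 higher and 3 lower, against 7 and 5 in the report), 3 for Tie2 against Cdh5 (2 and 1, against 2 and 0), 2 for Tie2 against Cd19 and 1 for Cdh5 against Cd19. Fitting the 2 compared groups alone gave 0 for Cd19 (268 unadjusted), 42 for Cdh5 and 3418 for Tie2 against WT, 1 for Tie2 against Cdh5 and 0 for Tie2 and Cdh5 against Cd19 (1738 and 1036 unadjusted). Averaging WT-1 and WT-1b gave 3 for Cdh5 and 5 for Tie2. A replicate block gave 3 for Cdh5 and 5 for Tie2 against WT, 2 for Tie2 and 0 for Cdh5 (3341 unadjusted) against Cd19, 5 for the F test and a log2 change of -0.55 for Gabbr1 in Cd19, but the numbers do not pair the libraries: of 15 same-numbered pairs 1 correlated above 0.1, and 1 of 11 libraries correlated best with its own number. Leaving out Cd19-1 gave 5102 for Cdh5 and 5232 for Tie2 against WT and 5 for Tie2 against Cdh5. In these comparisons Cd19-1 enters only the estimate of the spread. With rescaling as well, counts were 15 for Cdh5 against WT, 4 for Tie2 against Cdh5 (3 higher and 1 lower) and 2 for Tie2 against Cd19, with 1 higher and 1 lower for Cdh5 against Cd19, and without WT-2 too they were 8 for Cdh5 (2 higher) and 7 for Tie2 against WT (2 higher), 3 for Tie2 against Cd19 (2 higher) and 1, lower, for Cdh5 against Cd19. Next, each library of the 2 compared groups was left out in turn. Against WT this gave 3 to 8 genes for Cd19, 4 to 6 for Cdh5 and 5 to 11 for Tie2. Between deletions it gave 2 to 6 for Tie2 against Cdh5, 2 to 6 for Tie2 against Cd19 and 0 to 4 for Cdh5 against Cd19. The 0 came without Cd19-2 or cdh5-3, with 5658 and 1269 unadjusted. With each of all 12 libraries left out, the F test gave 6 to 82 (82 without Cd19-1) and the lists 25 to 36 calls. With an estimated correlation the 32 list calls became 0. With libraries of the compared groups left out in turn, 1106 values of named genes kept their direction and side of the threshold. Of the others, 27 lost and 8 gained a pass and 5 turned direction. Of the list calls, 156 were kept and 36 lost. In comparisons without Cd19, leaving out Cd19-1 kept 41 values of named genes and gave 88 a pass. Of their list calls, 19 were kept and 5 lost. Among single genes that turned direction, none past the threshold, Gabbr1 in Cd19 was 0.15 and became -0.36 with a pseudocount of 0.1, -0.0439 with median-of-ratios scaling and -0.31 among protein-coding genes, and ran from -0.35 to 0.87 with each library left out. Gphn in Cd19 ran from -0.93 to 0.0659 (without Cd19-1) and Stab2 in Cd19 from -0.0486 (without Cd19-3) to 2.54. In Cdh5, under median-of-ratios scaling, protein-coding genes, rescaling without Cd19-1 and without WT-2 too, Gphn was -0.13, -0.0593, -0.14 and -0.15, Rgcc -0.28, -0.18, -0.29 and -0.43, and Car2 -0.22, -0.11, -0.23 and -0.0208, and Csf2rb2 was -0.12 under the last. Nfe2 in Tie2 was -0.11 under the first and next to last and -0.00387 under the last. These settings remove the shift of the median gene or, among protein-coding genes, reduce it (to 0.15 in Cdh5 and 0.20 in Tie2). Ribosomal proteins turned lower under the same 4 settings, with adjusted p = 0.196, 0.445, 0.0821 and 0.909 in Cdh5 and 1.2e-05, 0.000148, 4.9e-06 and 0.00999 in Tie2. By fry, which tests on the unshifted scale, 12 of the 32 list calls were kept and 15 lost, among them histones in Tie2 (adjusted p = 0.308) and Cdh5 (0.446) and granulocyte-monocyte genes in Tie2 (0.985), and the other 5 turned. The lists of granulocyte-monocyte (adjusted p = 0.559), megakaryocyte (0.345), erythroid (0.559) and eosinophil, basophil and mast cell genes (0.886) in Cdh5 and of erythroid genes in Tie2 (0.471) leaned higher. With no filter, granulocyte-monocyte (0.818), megakaryocyte (0.755) and erythroid genes in Cdh5 (0.745) and erythroid genes in Tie2 (0.485) did so too. The lowest exact p for Gad1 and Gad2 stayed at 0.4. Depth was unknown, so what it limits could not be computed.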

Other observations

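The test of the DNA around Gad1 and Gad2 was set before its result was seen. The rescaled values below, which leave out Cd19-1, were chosen after the data had been seen.

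Among the immunoglobulin genes, Ighv11-2 and Igkv14-126, whose products pair in many antibodies of B-1 cells, varied widely between libraries. Ighv11-2 averaged 49.0 ± 44.7 TPM in WT, 341 ± 340 in Cd19, 744 ± 703 in Cdh5 and 1445 ± 633 in Tie2, and Igkv14-126 averaged 41.4 ± 36.8, 609 ± 661, 497 ± 429 and 1182 ± 473 TPM. Jchain, which joins the chains of secreted IgM and IgA, averaged 16.6 ± 19.6, 72.5 ± 39.96, 140 ± 88.0 and 365 ± 87.0 TPM. Against WT none of these 3 passed in Tie2 (adjusted p = 0.0594, 0.0594 and 0.0511) or by the F test (adjusted p = 0.234, 0.234 and 0.211). Immunoglobulin segments held 0.107% ± 0.146 of the TPM in WT and 1.72% ± 0.293 in Tie2.

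After rescaling, 29 of 30 mitosis genes were lower in Cdh5 than in WT and 10 fell when adjusted over the list alone (median -0.52, camera adjusted p = 1.5e-10, and adjusted p = 0.311 with an estimated correlation). In Cd19, 23 of 30 were lower and 5 fell when adjusted over the list alone (median -0.20, adjusted p = 0.00331, and adjusted p = 0.547 with an estimated correlation). In Tie2, 28 of 30 were lower and none fell when adjusted over the list alone (median -0.23, adjusted p = 0.000403, and adjusted p = 0.397 with an estimated correlation). Of 63 nuclear-encoded respiratory chain genes, 59 were lower in Tie2 (median -0.32, adjusted p = 2.5e-09, and adjusted p = 0.335 with an estimated correlation) and 54 in Cdh5 (median -0.24, adjusted p = 0.000308, and adjusted p = 0.63 with an estimated correlation), and 50 were higher in Cd19 (median 0.22, adjusted p = 0.00129, and adjusted p = 0.586 with an estimated correlation). Type I interferon genes were higher in 32 of 41 in Tie2 (median 0.37, adjusted p = 0.00111, and adjusted p = 0.401 with an estimated correlation) and 31 of 41 in Cd19 (median 0.47, adjusted p = 0.00126, and adjusted p = 0.543 with an estimated correlation), and 24 of 41 in Cdh5, where the list did not pass (median 0.12, adjusted p = 0.184, and adjusted p = 0.75 with an estimated correlation). None of these 3 lists was called against WT without rescaling.

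A hypothesis was that DNA from another strain around the floxed alleles could set nearby genes apart from WT. The 80 tested genes nearest to Gad1 and Gad2 had a median absolute moderated t of 1.10 in the mean of the 3 deletions against WT, at percentile 52.9 of 10000 random pairs of windows (median 1.09), and none of the 20 genes changed in that comparison was among them. With 20 of 14476 genes changed, finding none among 80 was likely in any case. Taken apart, the median was 1.33 near Gad1 and 0.94 near Gad2, and these were not ranked against windows. The pooled test gave no sign of such an effect.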
